A study of Mus musculus with 4 samples.

How the data were processed

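The samples were 4 arrays of total RNA from mouse mesangial cells, 2 labelled low glucose and 2 labelled TGF-beta1. The group of each array came from its title. Replicates were numbered within each group, and these numbers pair no arrays. The titles also carried repeat tags: low glucose replicate 1 and TGF-beta1 replicate 2 had the same unnumbered tag, low glucose replicate 2 had a numbered one and TGF-beta1 replicate 1 had none. What the tags mean is not given in the sources used here, and no pairing was planned from them. The doses, times and glucose levels are not given in the sources used here. The authors deposited 1 value per probe set and array, a linear intensity, and how they summarised the probes and scaled the arrays is not given in the sources used here. Over the 4 arrays, 0 values were missing and 1 was 0. No 2 arrays shared more than 1 identical value, so each was counted as a separate sample.

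Gene names came from the platform annotation of the probe sets. Leaving out 64 control probe sets, 34945 of 45037 had 1 gene symbol, 932 had several and 9160 had none here. Of those with 1 symbol, 34754 had a gene identifier found in a reference gene table, and 0 symbols changed through it. Probe sets with several symbols or none were not named.

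From the deposited intensities, log2(intensity + pseudocount) was computed, the pseudocount being the 25th percentile of all values, 46.88. The array medians then differed by up to 0.227, above the limit of 0.1 set beforehand, so quantile normalisation followed. Probe sets at or above the 40th percentile of the mean log2 value were kept (27022). For each gene the probe set of highest mean was tested, which left 13565 genes. The test was limma's lmFit and eBayes with an intensity trend, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05 (limma 3.58.1, R 4.3.3; figures with matplotlib 3.10.9, Python 3.11.15). Gene lists (27) were tested with camera, two-sided, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists with at least 5 tested members. The design, lists, named genes and most alternatives were fixed before the data were examined. Members of lists were also adjusted over the list alone.

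Genes were named by a rule fixed beforehand. It took the 12 genes with the largest rise and the 12 with the largest fall among genes past the threshold, or, as happened here because fewer than 5 passed, the 12 of lowest unadjusted p in each direction, without symbols that are only clone or model names. To these it added up to 4 members of each list with the largest absolute moderated t, and a fixed set of TGF-beta and glucose genes and controls, of which 2 had no probe set with a single symbol here. Genes given without a value to complete a small count, the members Col7a1, Slc2a1, Arrdc4, Hspa5, Cdh16, Pax8 and Lrp2, and Fgf21, Tnnt2, Sostdc1 and the genes of lists written later were named outside that rule, chosen after their values were seen.

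Array pairs were found after the values were seen, from 18 probe sets of hybridisation spike-ins, which hold no RNA of the cells: each low glucose array was paired with the TGF-beta1 array nearest to it in these values. Pairing the arrays with the same repeat tag, and so the other arrays with each other, gives the same pairs. The array pair was then added as a block to the same limma fit and to camera, and each TGF-beta1 array was set against the low glucose array of its pair. In this balanced layout the block leaves each log2 difference as it was and changes its standard error, whose median was 0.183 without and 0.0719 with the block. The blocked fit has 1 residual degree of freedom and an infinite prior, so a gene's standard error depends on its brightness alone. The fit without the block has 2 residual degrees of freedom and a prior of 2.79, and the blocked fit was repeated with that prior, and the other with an infinite one. A fit with the pair as a random effect was tried and gave no usable estimate of the correlation within pairs.

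Both fits were tested on simulated arrays with the real means and the real pair differences, with 67, 67 and 66 genes changed by 0.25, 0.5 and 1 on the log2 scale. Without the block, 0% of the changed genes were called at a log2 change of 0.25, 0.5 or 1, and 0 unchanged genes. With the block and an equal spread at a given brightness, 91% were called at 0.25 and 100% at 0.5 and at 1, with 15 unchanged genes called. With a spread that varied between genes, 61.2%, 98.5% and 100% were called, with 24 unchanged genes. A list raised by 0.3 was called by camera in each simulation, with 0 of the 26 other lists. The simulated genes varied independently of each other, so this does not test whether the preset correlation suits the real lists.

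The alternatives were other pseudocounts, a floor in place of a pseudocount, the authors' scaling, median centring, no filter or a filter at the 60th percentile, all kept probe sets, leaving out probe sets that may match several transcripts, another variance model, a threshold of 0.1, camera with an estimated correlation, fry, and leaving out each array in turn. The other variance model was not run for lists, since camera has no such option. The array-pair block, alone and with each of these except leaving out an array, and the change of prior were chosen after seeing the data. A single array left in a group was assumed to vary like the other group. For the patterns weighed in the closing section, other tests were looked at first and replaced: the sign agreement of probe sets and the levels of endoplasmic reticulum chaperones. Tests of more glucose in the TGF-beta1 cultures and of a different share of epithelial cells were dropped, since the patterns that prompted them fixed their outcome. Another probe set of a named gene that passed is given where its difference was under 0.5 times that of the tested one.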

Results

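RNA described as that of cultured mouse mesangial cells was measured on 4 one-colour oligonucleotide arrays. Mesangial cells are the contractile cells that hold the capillary loops of the kidney glomerulus together. Per the labels, 2 arrays carried RNA of cells kept in low glucose and 2 carried RNA of cells given transforming growth factor beta 1 (TGF-beta1), a cytokine that drives matrix accumulation in the glomerulus. The comparison asks which genes differ between the TGF-beta1 and the low glucose arrays. The labels give no glucose level for the TGF-beta1 arrays. A difference in glucose therefore cannot be told apart from an effect of TGF-beta1 for any gene. The deposited values were linear intensities, with array medians of 96.75 and 78.28 in low glucose and 80.32 and 99.62 in TGF-beta1. Differences are given below on the log2 scale after a pseudocount of 46.88 and quantile normalisation, as TGF-beta1 minus low glucose over 13565 genes, and they understate the change of dim genes. Nothing in the labels says that the arrays of a group came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. The number of arrays limits the precision.

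The 4 arrays sorted into 2 pairs that each held 1 array of either group. Low glucose replicate 1 and TGF-beta1 replicate 2 correlated across genes at r = 0.988 (array pair 1), and low glucose replicate 2 and TGF-beta1 replicate 1 at r = 0.99 (array pair 2), while the arrays of the same group correlated at 0.955 in both groups. The genes on an array are not independent replicates. The pairs had been made from the 18 probe sets of the hybridisation spike-ins, control transcripts added to every sample. Their mean absolute log2 difference was 0.0535 and 0.0888 within the pairs and at least 0.972 between them, an order that the pairing largely fixed. Fitted without a block, the division into array pairs separated 5597 genes and the division into low glucose and TGF-beta1 separated 0, at an adjusted p under 0.05 with limma.

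**Figure D1:**
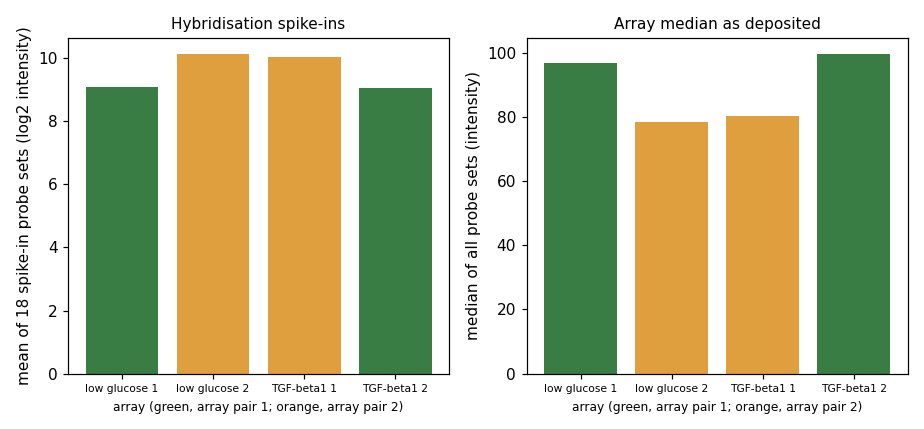
Mean log2 intensity of the 18 hybridisation spike-in probe sets (left) and median intensity of all probe sets as deposited (right), 1 bar per array, coloured by array pair. Both arrays of pair 2 have brighter spike-ins (10.14 and 10.05 against 9.08 and 9.06) and lower medians (78.28 and 80.32 against 96.75 and 99.62) than both arrays of pair 1.

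Most tested TGF-beta/SMAD response genes (17 of 25) were higher in TGF-beta1 and 4 Id genes were lower, and Txnip was lowered more than any other tested gene. The largest rises by the rule for named genes were those of Ctsw, a cysteine protease of the cathepsin family, at 1.77 ± 0.064 (3.41-fold; 1.67 and 1.87 within the pairs), Atf3, a stress-induced transcription factor, at 1.34 ± 0.083 (1.48 and 1.20), Pmepa1, a TGF-beta-induced inhibitor of SMAD signalling, at 1.29 ± 0.083 (1.27 and 1.30) and Anxa8 at 1.27 ± 0.083 (1.30 and 1.23). Txnip, an arrestin that restrains glucose uptake, fell by 1.61 ± 0.078 (3.04-fold; -1.70 and -1.51), Selenbp1 by 1.29 ± 0.069 (-1.37 and -1.21), Agt, the precursor of the angiotensins, by 1.16 ± 0.076 (-1.30 and -1.03) and Id3 by 0.99 ± 0.076 (-1.09 and -0.89). Values after ± are standard errors of the limma fit with the array pair as a block, with n = 2 arrays per group. Here "rose" and "fell" mean an adjusted p under 0.05 in that fit. On simulated arrays, unchanged genes made up a larger share of its calls than this threshold.

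With the array pair as a block, 2503 of the 13565 genes passed an adjusted p of 0.05 with limma. Of these, 1070 were higher and 1433 lower in TGF-beta1. The share that was higher was 42.7%, against 46.1% with the authors' scaling and 33.5% of 2619 genes with arrays centred on their medians. Of the 2503 genes, 2489 had the same sign within both pairs. Opposite signs need a larger gap between the within-pair differences than most genes showed. The call therefore largely fixed this agreement, and it is no separate result. The block was added after the values were seen. The fit planned before the data were examined, without the block, called 0 genes with limma, and its smallest adjusted p was 1. At an unadjusted p under 0.05 it gave 271 genes, 173 higher and 98 lower. Chance would give 678 if the 4 arrays were exchangeable, which the array pairs show they were not. The remaining division of the arrays, which crosses both group and pair, gave 1. The next calls are those of the planned fit of TGF-beta1 against low glucose without the block. Without 1 array it called 9 genes (without low glucose replicate 1), 9 (without low glucose replicate 2), 0 (without TGF-beta1 replicate 1) and 2 (without TGF-beta1 replicate 2, Ctsw and Fgf21). The blocked fit leaves 1 residual degree of freedom, so every gene took the spread of genes of its brightness, with an infinite prior degrees of freedom. Its calls rest on that: with the prior of the fit without the block, 2.79 degrees of freedom, the blocked fit called 0 genes with limma, and 2242 had an unadjusted p under 0.05. Of the 2503 genes, 1364 had both arrays of one group above both of the other. Over all genes that share was 20.9%, against 6.1% in the remaining division, 73% between the array pairs and the 33.3% that chance gives for 4 exchangeable arrays.

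Sizes did not depend on the block. A rise of at least 0.5 was seen in 162 genes and a fall of that size in 83. When the 4 arrays were divided the remaining way, 0 genes differed by 0.5, and the largest difference was 0.41. That difference is 0.5 times the gap between the 2 within-pair differences. All 245 genes therefore had to have the same sign within both pairs, and this is no separate result. Of 113 named genes past the threshold with the block, 31 changed in size by over 1.5 times when 1 array was left out. Leaving out 1 array, which was done without the block, unbalances the array pairs between the groups. Part of the difference between pairs then enters the values of genes and lists. Such a move alone does not show that the difference within pairs was unstable. The differences within pair 1 and within pair 2 correlated across genes at r = 0.708 (Spearman's rho = 0.567).

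**Figure D2:**
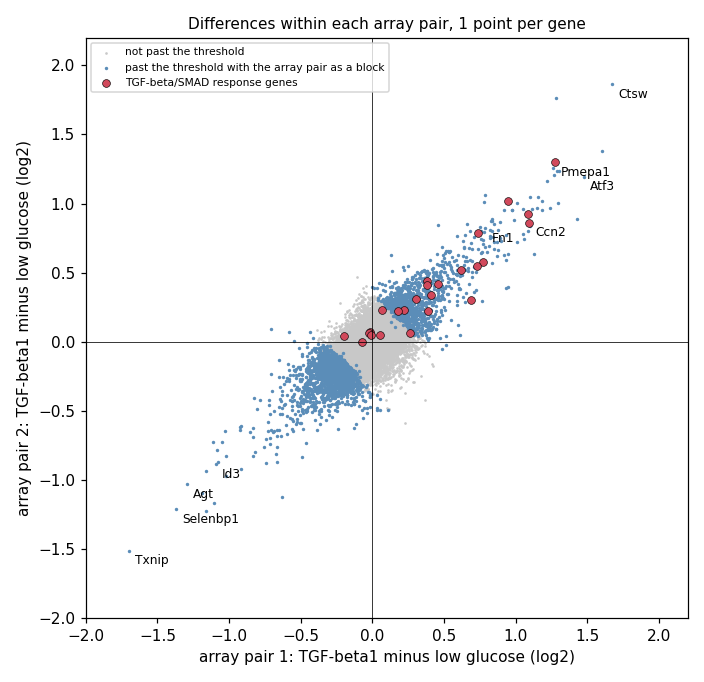
Difference of TGF-beta1 from low glucose within array pair 1 (horizontal, log2) against that within array pair 2 (vertical, log2), 1 point per gene; blue, genes past the threshold with the array pair as a block; red, TGF-beta/SMAD response genes. Ctsw lies at 1.67 and 1.87 and Txnip at -1.70 and -1.51, and 23 of the 25 red points have a mean difference above 0.

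Among the other genes of lowest unadjusted p, none of which passed without the block, Jun, a subunit of the AP-1 transcription factor, rose by 1.10 ± 0.080 and Dusp1, a phosphatase that switches off MAP kinases, by 1.06 ± 0.076. Tm4sf1 rose by 1.01 ± 0.082, Rhob, a small GTPase of the actin cytoskeleton, by 0.96 ± 0.082 and Zfand2a by 0.82 ± 0.080. The genes that fell included Rasl11b at -0.98 ± 0.082, Ntn4, a basement membrane netrin, at -0.94 ± 0.069 and Npr3, the clearance receptor of natriuretic peptides, at -0.93 ± 0.071. Rida fell by 0.83 ± 0.072, Mettl7a1 by 0.81 ± 0.081 and Ptgds, a prostaglandin D synthase, by 0.73 ± 0.081. Acaa2, an enzyme of mitochondrial fatty acid oxidation, fell by 0.73 ± 0.083 and Gstm2, a glutathione transferase, by 0.53 ± 0.069. Other probe sets of Npr3 showed smaller differences, of -0.43 and -0.05, and 1 other of Ntn4 showed -0.29, while 1 of Zfand2a was at 0.15.

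For 27 gene lists fixed before the data were examined, each list was set against the other tested genes with camera, in the fit without the block. With camera's preset correlation, 12 lists passed an adjusted p of 0.05, 6 shifted up and 6 down, and the same number passed with the array pair as a block. With an estimated correlation 0 passed, and that adjusted p stands beside each of the 12 lists and each list that another choice called. The directional test of fry called 0 lists, and its mixed test, which asks for change in either direction, called 2: TGF-beta/SMAD response genes and cell cycle inhibitors, both at an adjusted p of 0.0163. Unless another count is given, the counts adjusted over the list alone were those given for all genes. In the limma fit without the block, adjusted over the list alone, 5 TGF-beta/SMAD response genes passed, 1 gene each of the Id, inflammatory, unfolded protein and epithelial lists, and 0 of the other lists.

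TGF-beta/SMAD response genes rose as a group: 17 of 25 rose, 0 fell and 8 did not pass, and 18 rose when adjusted over the list alone. Their median was 0.38 (0.38 and 0.31 within the pairs), with a camera adjusted p of 1.9e-19 and an adjusted p of 0.198 with an estimated correlation. Besides Pmepa1, Bhlhe40 rose by 1.01 ± 0.081, Junb by 0.98 ± 0.081, and Ccn2, the matricellular connective tissue growth factor, by 0.98 ± 0.065. Skil, a SMAD co-repressor, rose by 0.64 ± 0.082 and Smad7, the inhibitory SMAD, by 0.50 ± 0.072. The Id family and BMP targets had 1 member that rose (Hes1) and 4 of 10 that fell, with 5 that did not pass, and the 4 that fell were the Id genes, inhibitors of basic helix-loop-helix factors. Id3 fell by 0.99, Id2 by 0.71 ± 0.078, Id1 by 0.43 ± 0.082 and Id4 by 0.25 ± 0.077. The list's mean was -0.19 and its median -0.03 (-0.08 and 0.01 within the pairs), with a camera adjusted p of 0.0262 and an adjusted p of 0.319 with an estimated correlation. Its call ended without low glucose replicate 1 (adjusted p = 0.381 with camera) and without TGF-beta1 replicate 1 (0.341), where the medians were 0.15 and 0.11. The median was -0.20 without low glucose replicate 2 and -0.18 without TGF-beta1 replicate 2. Skil was at 0.38 without low glucose replicate 1. Smad7 was at 0.22 without low glucose replicate 1 and 0.77 without low glucose replicate 2. Id2 was at -0.47 without low glucose replicate 2.

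The ligands, receptors and antagonists of the TGF-beta superfamily moved both ways and were not called (camera adjusted p = 0.623): 8 of 32 rose, 6 fell and 18 did not pass. Fst, which binds activin, rose by 0.94 ± 0.082, Acvr1, a type I receptor, by 0.64 ± 0.069 (0.11 on another probe set) and Thbs1, an activator of latent TGF-beta, by 0.41 ± 0.082, while Tgfbr3, the co-receptor betaglycan, fell by 0.65 ± 0.082 (-0.14 on another probe set). Tgfb1 itself differed by 0.04 ± 0.078 (-0.04 and 0.12 within the pairs; adjusted p = 0.769 with limma and the block). Acvr1 was at 0.35 without low glucose replicate 1 and 0.41 without TGF-beta1 replicate 1. Thbs1 was at 0.25 without TGF-beta1 replicate 2.

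The lists of collagens, matrix glycoproteins and collagen maturation were not called in the planned fit, which does not show that they were unchanged. Of 17 collagens 4 rose, 1 fell and 12 did not pass (camera adjusted p = 0.229). Col4a4 rose by 0.58 ± 0.076 (0.23 on another probe set), Col5a1 by 0.54 ± 0.076 (0.16), Col4a3 by 0.41 ± 0.064 (0.16) and Col7a1 by 0.25 ± 0.064, Col4a6 fell by 0.31 ± 0.080, and Col1a1 (0.11 ± 0.065) and Col4a1 (0.04 ± 0.077) did not pass. Col1a1 and Col4a1 were dim, with mean log2 values of 7.49 and 6.93, so a change in them may be understated, although Col4a3 passed at 7.61. With all kept probe sets in place of 1 per gene the collagens were called (camera adjusted p = 0.00522). The adjusted p was 0.467 with an estimated correlation and 1 probe set per gene. Of 23 matrix glycoproteins and proteoglycans 2 rose, 3 fell and 18 did not pass (camera adjusted p = 0.609; 0.0476 without low glucose replicate 1; 0.792 with an estimated correlation). The 2 that rose were Fn1, fibronectin, at 0.80 ± 0.072, with 0.66 on its other probe set, and Tnc, tenascin C, at 0.54 ± 0.071, while Nid2 fell by 0.63 ± 0.081 and Lamb2, a laminin chain, by 0.21 ± 0.068, as did Fmod. Among 16 genes of collagen maturation and cross-linking 3 rose, 1 fell (2 when adjusted over the list alone) and 12 did not pass (camera adjusted p = 0.623, direction up; mean 0.05, median -0.01, and between -0.11 and 0.15 when 1 array was left out). Lox, which cross-links collagen, rose by 0.64 ± 0.065 and Loxl1 by 0.34 ± 0.070 (0.02 on another probe set), and Plod2 rose as well. Pcolce, an enhancer of procollagen processing, fell by 0.28 ± 0.063, and Tgm2 was at -0.20 ± 0.078 without passing. Fn1 was at 0.52 without low glucose replicate 2. Col5a1 was at 0.35 without low glucose replicate 1 and 0.30 without TGF-beta1 replicate 1. Col4a3 was at 0.25 without low glucose replicate 1. Loxl1 was at 0.17 without low glucose replicate 2 and 0.17 without TGF-beta1 replicate 2. Lamb2 was at -0.35 without low glucose replicate 1, -0.06 without low glucose replicate 2 and -0.10 without TGF-beta1 replicate 2. Col4a6 was at -0.18 without TGF-beta1 replicate 2.

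Matrix proteases and their inhibitors shifted up, with 8 of 24 rising, 2 falling and 14 not passing, and a median of 0.05 (0.11 and 0.05 within the pairs; camera adjusted p = 0.000441, and an adjusted p of 0.284 with an estimated correlation). Plat, tissue plasminogen activator, rose by 0.76 ± 0.083 (its other probe set was at 0.09) and Adamts1 by 0.75 ± 0.083. Htra1 rose by 0.56 ± 0.080, Timp1, an inhibitor of metalloproteases, by 0.34 ± 0.080 and Ctsl by 0.27 ± 0.061, and those that fell were Reck and Mmp11. The list was not called without TGF-beta1 replicate 2 (camera adjusted p = 0.0746, median 0.05). Its median was 0.15 without low glucose replicate 1, 0.08 without low glucose replicate 2 and 0.145 without TGF-beta1 replicate 1. Smooth muscle and myofibroblast contractile genes also shifted up: 13 of 30 rose (15 when adjusted over the list alone), 0 fell and 17 did not pass. Their median was 0.16 (0.15 and 0.16 within the pairs; camera adjusted p = 5.28e-06, and an adjusted p of 0.319 with an estimated correlation). Without TGF-beta1 replicate 2 the median was 0.04 and the list was not called (camera adjusted p = 0.086). The median was also 0.04 without low glucose replicate 2 and 0.25 without TGF-beta1 replicate 1. Tagln, an actin-binding protein of smooth muscle, rose by 0.88 ± 0.071, Fhl2 by 0.59 ± 0.081, Pdlim7 by 0.59 ± 0.082, Tpm1 by 0.46 ± 0.072 and Acta2, smooth muscle actin, by 0.32 ± 0.066. Actb, the cytoskeletal actin, was at 0.05 ± 0.039. Integrins and adhesion receptors were not called (camera adjusted p = 0.112; 0.00621 with all kept probe sets; 0.356 with an estimated correlation): 4 of 23 rose (5 when adjusted over the list alone), 1 fell and 18 did not pass. Cd44, the hyaluronan receptor, rose by 0.75 ± 0.083, Itgb1 by 0.26 ± 0.080 and Itgb3 by 0.25 ± 0.068, with Cdh2 as the other that rose. Itga1 fell, and Sdc4 was at 0.21 ± 0.083 without passing. Tpm1 was at 0.30 without low glucose replicate 2. Timp1 was at 0.22 without low glucose replicate 1, 0.12 without TGF-beta1 replicate 1 and 0.56 without TGF-beta1 replicate 2. Acta2 was at 0.18 without TGF-beta1 replicate 1. Itgb1 was at 0.45 without low glucose replicate 1, 0.07 without low glucose replicate 2, 0.48 without TGF-beta1 replicate 1 and 0.04 without TGF-beta1 replicate 2. Itgb3 was at 0.14 without TGF-beta1 replicate 1.

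**Figure D3:**
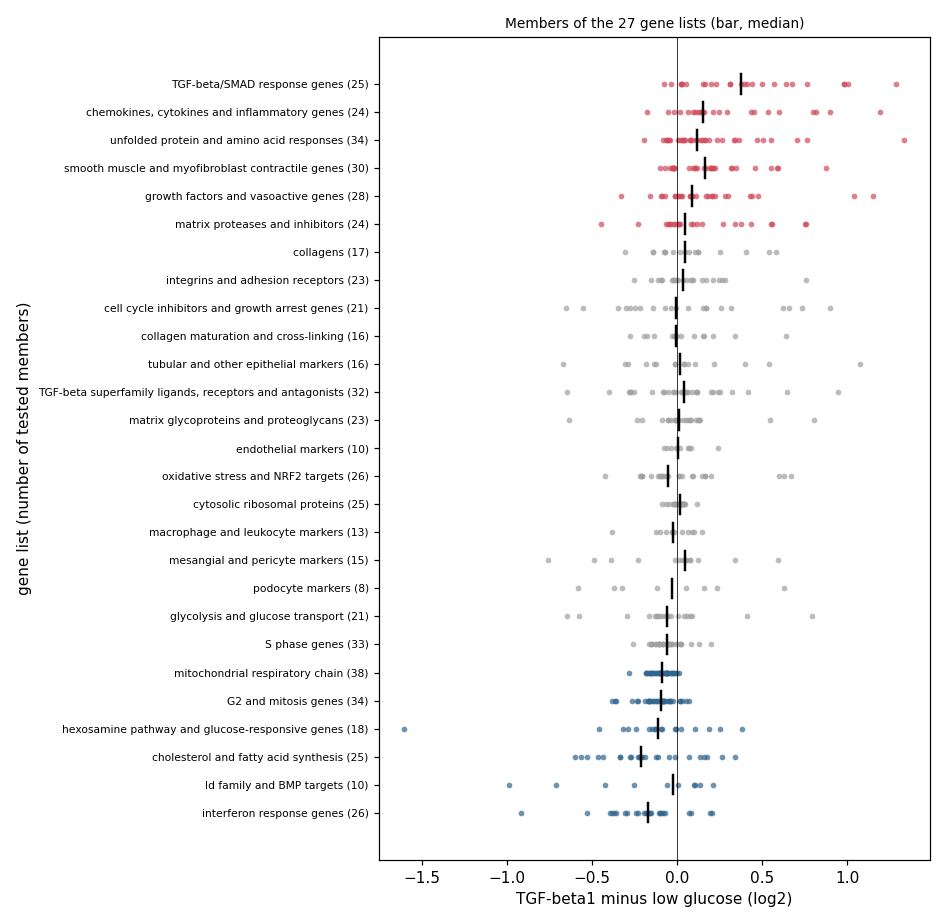
TGF-beta1 minus low glucose (horizontal, log2) for the tested members of each of the 27 gene lists, 1 point per gene and 1 row per list, ordered by the list's mean; black bars, list medians; red and blue, lists that camera with its preset correlation called up and down; grey, lists not called. The TGF-beta/SMAD list has the highest median (0.38) and the cholesterol and fatty acid list the lowest (-0.22).

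G2 and mitosis genes shifted down by a small amount: 0 of 34 rose, 6 fell and 28 did not pass, with a median of -0.10 (-0.10 and -0.12 within the pairs; camera adjusted p = 0.00012, and an adjusted p of 0.319 with an estimated correlation). Kif11, a mitotic kinesin, fell by 0.38 ± 0.067, Nusap1 by 0.37 ± 0.074, Mki67, a proliferation marker, by 0.36 ± 0.076 and Cenpe by 0.27 ± 0.064. The call ended without low glucose replicate 2 (camera adjusted p = 0.229, median -0.05) and without TGF-beta1 replicate 2 (0.262, median -0.09). S phase genes were not called (camera adjusted p = 0.0593, median -0.06, and -0.02 without TGF-beta1 replicate 2): of 33, Orc1 was the 1 that rose, by 0.20 ± 0.064, Ccne2 was the 1 that fell, by 0.26 ± 0.067, and 31 did not pass, Pcna (-0.09 ± 0.048) and Pole (-0.15 ± 0.081) among them. They were called with arrays centred on their medians (camera adjusted p = 0.0479), with no filter (0.044), with all kept probe sets (0.00638) and without probe sets that may match several transcripts (0.0474). The adjusted p was 0.319 with an estimated correlation. Cell cycle inhibitors and growth arrest genes changed in both directions, with 6 of 21 higher (8 when adjusted over the list alone), 7 lower and 8 not past the threshold (camera adjusted p = 0.45, direction up; mean 0.06, median -0.01, and down to -0.12 without low glucose replicate 1; 0.0427 without low glucose replicate 2; 0.768 with an estimated correlation). Cdkn1a, the inhibitor p21, rose by 0.74 ± 0.082, Btg2 by 0.66 ± 0.083 and Plk2 by 0.62 ± 0.079, while Sesn1 fell by 0.66 ± 0.068. Orc1 was at 0.07 without low glucose replicate 1, 0.33 without low glucose replicate 2, 0.06 without TGF-beta1 replicate 1 and 0.34 without TGF-beta1 replicate 2.

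Chemokines, cytokines and inflammatory genes shifted up, and interferon response genes shifted down. In the inflammatory list 11 of 24 rose (13 when adjusted over the list alone), 1 fell and 12 did not pass, with a median of 0.15 (0.20 and 0.16 within the pairs; camera adjusted p = 1.87e-10, and an adjusted p of 0.198 with an estimated correlation). Lcn2, the siderophore-binding lipocalin, rose by 1.19 ± 0.075, Ptgs2, cyclooxygenase-2, by 0.90 ± 0.069, Lif by 0.82 ± 0.064 and Tlr2 by 0.80 ± 0.076. The other Lif probe set was at 0.08. Il1b was the 1 that fell, by 0.18 ± 0.065, but its sign differed between the pairs (-0.43 and 0.07). The median was 0.23 without low glucose replicate 1 and 0.24 without TGF-beta1 replicate 1. In the interferon list 2 of 26 rose, 11 fell (16 when adjusted over the list alone) and 13 did not pass, with a median of -0.17 (-0.26 and -0.14 within the pairs; camera adjusted p = 3.3e-05, and an adjusted p of 0.319 with an estimated correlation). Ifit3 fell by 0.92 ± 0.074, the immunoproteasome subunits Psmb9 and Psmb8 by 0.53 ± 0.075 and 0.38 ± 0.080, and Ifit2 by 0.36 ± 0.073, while Oasl1 and Mx2 rose. The interferon call ended without low glucose replicate 2 (camera adjusted p = 0.0741, median -0.10) and without TGF-beta1 replicate 2 (0.263, median -0.01). The median was -0.29 without low glucose replicate 1 and -0.37 without TGF-beta1 replicate 1.

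Growth factors and vasoactive genes shifted up, with 10 of 28 higher, 1 lower and 17 not past the threshold, and a median of 0.09 (0.12 and 0.08 within the pairs; camera adjusted p = 0.000441, and an adjusted p of 0.482 with an estimated correlation). Hbegf, a ligand of the EGF receptor, rose by 1.15 ± 0.083, Pdgfb, a mitogen of mesangial cells, by 1.04 ± 0.080, Igfbp7 by 0.44 ± 0.077 and Bdnf by 0.28 ± 0.073. Other Igfbp7 probe sets lay between 0.02 and 0.20, and Vegfb was the 1 that fell. The call ended without low glucose replicate 2 (camera adjusted p = 0.154, median -0.02) and without TGF-beta1 replicate 2 (0.556, median -0.06). The median was 0.21 without low glucose replicate 1 and 0.24 without TGF-beta1 replicate 1.

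Genes of the hexosamine pathway and glucose-responsive genes shifted down: 3 of 18 rose, 5 fell (6 when adjusted over the list alone) and 10 did not pass, with a median of -0.11 (-0.13 and -0.07 within the pairs; camera adjusted p = 0.0267, and an adjusted p of 0.319 with an estimated correlation). The members moved apart within the list, and the list was not tested without Txnip, its largest change. Besides Txnip, Amdhd2 fell by 0.46 ± 0.082 and Nagk by 0.32 ± 0.082 (-0.10 on another probe set), both enzymes that handle N-acetylglucosamine, as did Oga and Arrdc4. Uap1, which makes UDP-N-acetylglucosamine, rose by 0.38 ± 0.079 (0.11 on another probe set), as did Gnpnat1 and Gfpt2. Gfpt1, the rate-limiting enzyme of the pathway, was at -0.10 ± 0.080 without passing, and its other probe set was at 0.09. The list was not called without low glucose replicate 2 (camera adjusted p = 0.188, median -0.06), without TGF-beta1 replicate 2 (0.263, median -0.01) or with all kept probe sets (0.116). Its median was -0.21 without low glucose replicate 1 and -0.24 without TGF-beta1 replicate 1. Glycolysis and glucose transport genes were not called (camera adjusted p = 0.316; 0.0353 with all kept probe sets; 0.482 with an estimated correlation): 2 of 21 rose, 3 fell and 16 did not pass. Hk2, a hexokinase, rose by 0.79 ± 0.082 and Slc2a1, a glucose transporter, by 0.41 ± 0.073, while Aldoc fell by 0.65 ± 0.079, Pdk1, a kinase that inhibits pyruvate dehydrogenase, by 0.58 ± 0.068 (-0.29 on another probe set) and Pfkm by 0.30 ± 0.083. Pfkm was at -0.19 without low glucose replicate 1. Pdk1 was at -0.37 without TGF-beta1 replicate 2.

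Cholesterol and fatty acid synthesis genes shifted down: 14 of 25 fell (15 when adjusted over the list alone), 4 rose (5) and 7 did not pass, with a median of -0.22 (-0.21 and -0.19 within the pairs; camera adjusted p = 0.000135, and an adjusted p of 0.284 with an estimated correlation). Idi1 fell by 0.60 ± 0.080, Elovl6, a fatty acid elongase, by 0.57 ± 0.082 (-0.08 on another probe set), Hmgcs1, an early enzyme of the mevalonate pathway, by 0.47 ± 0.063 and Mvk by 0.44 ± 0.079, while Srebf1, Acaca, Scd1 and Scd2 rose. Unfolded protein and amino acid response genes shifted up: 11 of 34 rose (12 when adjusted over the list alone), 0 fell (1) and 23 did not pass. Their median was 0.12 (0.14 and 0.10 within the pairs; camera adjusted p = 8.51e-08, and an adjusted p of 0.198 with an estimated correlation), and 0.18 without low glucose replicate 2. After Atf3, Ddit4 rose by 0.76 ± 0.081, Chac1 by 0.70 ± 0.080 and Trib3 by 0.55 ± 0.077, all targets of stress-induced transcription factors, while the endoplasmic reticulum chaperone Hspa5 was at 0.05 ± 0.056 without passing. Mitochondrial respiratory chain genes shifted down by little each: 37 of 38 lay below 0, 4 fell, 0 rose and 34 did not pass. Their median was -0.09 (-0.13 and -0.06 within the pairs; camera adjusted p = 3.05e-06, and an adjusted p of 0.319 with an estimated correlation; 0.0604 without low glucose replicate 1). Uqcrh fell by 0.28 ± 0.065, Cox6c by 0.18 ± 0.058 and Cox7a2 by 0.14 ± 0.049, as did Ndufv2, and Sdhd was at -0.18 ± 0.073. Oxidative stress genes and NRF2 targets were not called (camera adjusted p = 0.862, direction up; mean 0.03, median -0.06, and between -0.02 and 0.01 when 1 array was left out): 4 of 26 rose (5 when adjusted over the list alone), 3 fell (5) and 19 did not pass. Hmox1, a haem oxygenase, rose by 0.67 ± 0.082 (0.95 and 0.39 within the pairs), Gsto1 by 0.63 ± 0.064 and Mt2, a metallothionein, by 0.60 ± 0.075, as did Gclm, and Gstm1 fell by 0.43 ± 0.049, as did Gpx4 and Keap1. None of 25 ribosomal protein genes passed (camera adjusted p = 0.862; median 0.01, -0.02 with arrays centred on their medians, and between -0.05 and 0.03 when 1 array was left out), with Rps6 at 0.12 ± 0.082, Rpl19 at 0.04 ± 0.040, Rps15 at -0.07 ± 0.045 and Rps24 at -0.09 ± 0.049. Hmox1 was at 1.09 without TGF-beta1 replicate 1 and 0.25 without TGF-beta1 replicate 2. Gsto1 was at 0.40 without low glucose replicate 1. Hmgcs1 was at -0.28 without TGF-beta1 replicate 1.

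Markers of glomerular and other kidney cells moved gene by gene, and none of these lists was called. Of 15 mesangial and pericyte markers 2 rose, 4 fell and 9 did not pass (camera adjusted p = 0.779, direction up; mean -0.03, median 0.05, and between -0.02 and 0.09 when 1 array was left out): Fhl2 and Mcam rose, and Septin4 fell by 0.76 ± 0.075, Foxd1 by 0.49 ± 0.066 and Ptn by 0.39 ± 0.065, as did Rgs5. A second Ptn probe set was at 0.04. Of 8 podocyte markers 2 rose (3 when adjusted over the list alone), 3 fell and 3 did not pass (camera adjusted p = 0.616), with Podxl higher, Nes, nestin, at 0.63 ± 0.081 (0.11 on another probe set), Synpo at -0.58 ± 0.065 (0.07 on its other probe set), Plce1 at -0.37 ± 0.064 and Clic5 at -0.33 ± 0.071. Of 16 tubular and other epithelial markers 4 rose, 3 fell (4 when adjusted over the list alone) and 9 did not pass (camera adjusted p = 0.779). Cldn4, a tight junction claudin, rose by 1.08 ± 0.064 and the keratins Krt18 and Krt8 by 0.54 ± 0.061 and 0.40 ± 0.071, as did Grhl2, whereas Aqp1, a water channel, fell by 0.67 ± 0.076, as did Cdh16 and Lrp2. Of 10 endothelial markers 1 rose, 0 fell and 9 did not pass (camera adjusted p = 0.623). The 1 that rose was Eng, at 0.24 ± 0.068 (0.04 on another probe set), and Icam2 (0.08 ± 0.078), Ehd3 (0.07 ± 0.068) and Cldn5 (0.06 ± 0.077) did not pass. Of 13 macrophage and leukocyte markers 0 rose, 1 fell and 12 did not pass (camera adjusted p = 0.655): Csf1r fell by 0.38 ± 0.080, and Cd68 (0.14 ± 0.072), Laptm5 (0.10 ± 0.067) and Coro1a (-0.12 ± 0.073) did not pass. Nes was at 0.37 without low glucose replicate 2 and 0.36 without TGF-beta1 replicate 2. Eng was at 0.47 without low glucose replicate 1, 0.01 without low glucose replicate 2, 0.50 without TGF-beta1 replicate 1 and -0.02 without TGF-beta1 replicate 2. Clic5 was at -0.18 without low glucose replicate 2 and -0.19 without TGF-beta1 replicate 2. Plce1 was at -0.60 without low glucose replicate 1, -0.14 without low glucose replicate 2, -0.62 without TGF-beta1 replicate 1 and -0.13 without TGF-beta1 replicate 2. Csf1r was at -0.24 without low glucose replicate 1 and -0.20 without TGF-beta1 replicate 1. Ptn was at -0.07 without low glucose replicate 1 and -0.72 without low glucose replicate 2. Foxd1 was at -0.74 without low glucose replicate 1, -0.24 without low glucose replicate 2 and -0.26 without TGF-beta1 replicate 2. Synpo was at -0.35 without TGF-beta1 replicate 2. Septin4 was at -0.42 without TGF-beta1 replicate 2.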

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

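Which probe sets without a single gene symbol changed was asked after the data were seen. Of 3801 kept probe sets of this kind, none of which entered the comparison above, 191 were higher in TGF-beta1 with the array pair as a block (limma, adjusted over all kept probe sets) and 172 were lower. They were singled out because they had not been tested above, where 18.5% of the genes passed with the block. The fit that called them also had an infinite prior. Without the block, 22 had an unadjusted p under 0.05. They were not named, and no explanation was tested.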

How the results depend on the processing

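The array-pair block, alone or with another choice, was chosen after seeing the data. The repeat tag that the titles of 1 array of each group share gives the same pairs, but no pairing was planned from it. Without the block, the other planned choices of processing and threshold also gave 0 genes, and leaving out 1 array gave 0 to 9. The array-pair block gave 2503. It changed both the spread (median standard error 0.183 without, 0.0719 with) and the prior degrees of freedom (2.79 without, infinite with), and neither alone gave as many: the block with the prior of the other fit gave 0 genes, and the fit without the block but with an infinite prior gave 142, all among the 2503 and in the same direction. With the block, 11 further choices gave between 2356 and 3210 genes. Testing all kept probe sets gave 4285, which counts probe sets in place of genes. Of the 2503 genes, 2207 to 2503 were called in the same direction under each of these 12 choices. The largest prior was infinite under each, but a robust variance model, 1 of the choices, can give single genes a lower one. Leaving out an array with the block leaves no residual degrees of freedom, so it was not run. Without the block, leaving out 1 array unbalances the array pairs between the groups. The pair difference then enters the sizes, calls and directions of genes and lists.

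Of the 27 lists, 12 to 15 were called under each processing choice and 12 to 16 with the block. Without 1 array the count ranged from 6 (without TGF-beta1 replicate 2) to 11. Camera with an estimated correlation gave 0, fry's directional test gave 0, and with the block both gave 0. The cause was not tested. The self-test made list calls at this number of arrays with the preset correlation. Its genes varied independently of each other, so it does not test that preset.

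Test directions reversed in lists that were not called, where the cause was not tested. They are those of camera's statistic, not of the median. In the planned fit the medians were -0.0556 (oxidative stress), 0.0143 (ribosomal), 0.00537 (endothelial), -0.0327 (podocyte) and 0.0459 (mesangial). The oxidative stress and mesangial medians kept their sign under the choices listed next. Where directions reversed, the medians were, for oxidative stress genes, -0.0551 (50th percentile as the pseudocount), -0.0753 (arrays centred on their medians) and -0.0654 (all kept probe sets). For ribosomal proteins they were -0.0165 (centred) and -0.00502 (all kept probe sets), for endothelial markers -0.00574 (no filter), for podocyte markers 0.0525 (60th percentile filter), and for mesangial markers 0.0269 (60th percentile filter), 0.0387 (all kept probe sets) and 0.0459 (block). Leaving out 1 array moved the medians from -0.0899 to 0.116 for matrix glycoproteins, -0.114 to 0.147 for collagen maturation, -0.123 to -0.00656 for cell cycle inhibitors, -0.189 to 0.0252 for glycolysis, -0.0245 to 0.0063 for oxidative stress genes, -0.0537 to 0.0256 for ribosomal proteins, -0.0221 to 0.0867 for mesangial and -0.02 to 0.0501 for endothelial markers.

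Of 133 named genes, 113 passed with the block. Leaving out 1 array reversed 12, none past the threshold with the block except Eng, with ranges of -0.018 to 0.50 for Eng, -0.065 to 0.35 for Cd68, -0.13 to 0.37 for Rps6, -0.024 to 0.23 for Col1a1, -0.034 to 0.17 for Ehd3, -0.090 to 0.21 for Cldn5, -0.025 to 0.13 for Actb, -1.142e-05 to 0.086 for Col4a1, -0.15 to 0.24 for Tgfb1, -0.017 to 0.092 for Rpl19, -0.24 to 0.045 for Gfpt1 and -0.26 to 0.0096 for Coro1a. Of the 113, 31 changed in size by over 1.5 times without 1 array, the widest ranges for their size, besides that of Eng, being 0.040 to 0.48 for Itgb1, 0.061 to 0.34 for Orc1, -0.35 to -0.061 for Lamb2, -0.62 to -0.13 for Plce1 and -0.72 to -0.069 for Ptn. Within array pairs 1 and 2, Itgb1 was at 0.30 and 0.23, Orc1 at 0.19 and 0.21 and Eng at 0.27 and 0.21. Lamb2 was at -0.16 and -0.25, Plce1 at -0.38 and -0.36 and Ptn at -0.65 and -0.13 within these pairs. Without probe sets that may match several transcripts, Laptm5 turned to -0.035 and Rps24 to 0.081. Within array pair 1 the sign differed for Cldn5 (-0.0062), Tgfb1 (-0.038), Rpl19 (-0.0043), Pcna (0.0041) and Coro1a (0.012), and within pair 2 for Ehd3 (-0.0068).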

Other observations

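All tests in this part were chosen after the results they bear on were seen, and the 5 lists (AP-1 genes, phosphatases, EGF receptor ligands, clock genes and proximal tubule genes) were written after the values of some members were known. Each list was also tested without the members that stood among the named genes or the listed largest changes, which takes out its largest values. Of 13 genes of the AP-1 transcription factor family 11 rose, 0 fell and 2 did not pass, with a median of 0.73 (camera adjusted p = 1.54e-22 over the 5 lists, and an adjusted p of 0.0445 with an estimated correlation). Without Atf3, Jun, Junb and Fosl1, 7 of 9 rose, with a median of 0.44 (camera adjusted p = 1.81e-10, and an adjusted p of 0.102 with an estimated correlation). Besides Atf3, Jun and Junb, Fosl1 rose by 1.26 ± 0.080, Maff by 0.84 ± 0.081, Fosl2 by 0.79 ± 0.077 and Fos by 0.73 ± 0.081. Of 20 dual-specificity phosphatases, which remove phosphate from MAP kinases among other targets, 8 rose, 0 fell and 12 did not pass (median 0.13; camera adjusted p = 1.54e-07, and an adjusted p of 0.0687 with an estimated correlation). Without Dusp1, Dusp2, Dusp4 and Dusp5, 4 of 16 rose and the list was not called (camera adjusted p = 0.0549; 0.024 with the array pair as a block; 0.333 with an estimated correlation). The largest rises were in Dusp2 at 1.24 ± 0.066, Dusp5 at 1.10 ± 0.074, Dusp1 at 1.06, Dusp4 at 0.99 ± 0.071 and Dusp6 at 0.82 ± 0.082. Of these lists' members, 2 AP-1 genes and 0 phosphatases also stood in a list fixed beforehand.

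Of 4 EGF receptor ligands, Hbegf alone passed, and it rose (camera adjusted p = 0.101; 0.00943 with the array pair as a block; 0.345 with an estimated correlation). Circadian clock genes moved both ways, with 6 of 16 higher, 2 lower and 8 not past the threshold (camera adjusted p = 0.439; 0.368 with the array pair as a block; 0.494 with an estimated correlation). Nfil3, a repressor of clock output genes, rose by 0.80 ± 0.064, while Dbp and Tef, activators of such genes, fell by 0.81 ± 0.064 and 0.48 ± 0.082. Of 11 proximal tubule genes 1 rose, 4 fell and 6 did not pass (camera adjusted p = 0.0861; 0.00206 with the array pair as a block; 0.345 with an estimated correlation). Without such members, none of these 3 lists was called (camera adjusted p = 0.897, 0.247 and 0.96 in this order), and with the array pair as a block the clock list was (0.0483), with an adjusted p of 0.438 with an estimated correlation and no block. Enpep, the aminopeptidase that cleaves angiotensin II, fell by 1.14 ± 0.064, and Aqp1, Mme and Lrp2 were the others that fell, while Fbp1 rose. Genes of kidney epithelium had log2 values of 10.98, 10.98, 10.78 and 10.56 for Cdh16 and 9.71, 9.51, 9.46 and 9.48 for Pax8 on low glucose replicates 1 and 2 and TGF-beta1 replicates 1 and 2. Of the named mesangial markers, mean log2 values were 7.41 for Foxd1, 7.58 for Ptn, 8.73 for Septin4 and 9.28 for Fhl2. Contractile genes ran from 6.86 (Myl9) to 11.78 (Cnn3), with Acta2 at 7.45 and Des at 7.54. The brightness of a probe set depends on its sequence, so these values do not rank genes against each other. That the cells were mesangial is taken from their description and was not tested. Large changes outside the rule for named genes, chosen after their values were seen, were rises of Fgf21, a stress-induced hormone, by 1.52 ± 0.064 and of Tnnt2, cardiac troponin T, by 1.49 ± 0.067, and a fall of Sostdc1, an antagonist of BMP and Wnt signals, by 1.14 ± 0.065.

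The arrays sorted by array pair, not by group. RNA levels of the cultures were argued against as the whole cause: over 5926 genes with at least 2 kept probe sets, the pair difference of the brightest correlated with that of the next at r = 0.202 (95% interval 0.178 to 0.226, across genes, which are not independent), against r = 0.66 (0.645 to 0.674) for the TGF-beta1 difference, although the pair difference had the larger SD (0.392 against 0.185). A labelling or hybridisation difference between the pairs remains a candidate explanation. The spike-ins differed by at least 0.972 between pairs. The pairs were made from these values, though the shared repeat tag, from which no pairing was planned, gives the same pairs. Control signals that hold no RNA of the cells thus did differ between these pairs. Whether a labelling or hybridisation difference made the genes sort by pair was not tested. RNA degradation could not be told apart from such a difference: the 3' over 5' signal of the actin control was 0.257 higher in pair 2 on the log2 scale, but that of the GAPDH control was not (-0.054).

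Txnip fell by 1.61. A lower glucose level in the TGF-beta1 cultures, from the medium or from faster use, stays open as a candidate explanation next to an effect of TGF-beta1: Arrdc4, which glucose raises through the same transcription factors, fell as well, by 0.24 ± 0.064. The labels give no glucose level for the TGF-beta1 arrays, so these cannot be told apart.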
